A study of Mus musculus with 16 samples.

How the data were processed

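RNA was measured on 16 Illumina bead arrays of biotin-labelled cRNA from mouse primary hepatocytes and primary pancreatic islets, with 4 arrays in each of 4 groups. Per the labels, hepatocytes received 200 nM and islets 10 nM of FK866, an inhibitor of the NAD-producing enzyme NAMPT, and the control cells received 0.1% DMSO, all for 48 h. Groups and replicate numbers came from the sample titles. The labels do not say whether replicates were separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

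The intensity of each probe was deposited on a linear scale with negative values, and by its values had a background subtracted and no normalization between arrays. The deposited detection p-value of each probe stood in the column after each signal and decreased with that signal. The deposited normalized table holds a score for each gene symbol. By its values this score is the log10 signal of a gene, with signals below 1 set to 1, centred and scaled to mean 0 and SD 1 in each array. The authors' scanner software, array annotation and normalization tool are not given in the sources used here. The design had allowed for expression values in that table, and because it held scores it was used for gene names and as an alternative scale only.

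The intensity table pairs no probe with a gene, so the 25697 probes were named through the score table. For a symbol, the probe or mean of probes was sought whose log10 signals match the scores over the arrays of a tissue within 1e-08. This last search matched 15839 of 18111 symbols, 11408 with 1 probe and 4431 with several, and named 22438 probes. Of the probes detected on at least 4 arrays, 11339 of 11361 in hepatocytes and 11777 of 11803 in islets were named. Over a stretch of 5015 genes of the score table, from Pmpcb to Il22ra2, the hepatocyte and islet values of a symbol matched different probes, displaced by 1 position. The hepatocyte naming was used there, and the islet scores were moved by 1 position before use. The value table of the series matrix held 18105 genes, 6 fewer, with values equal to the score table, so it was not run as an alternative. Of the symbols, 14306 were current in a RefSeq gene table of assembly GRCm38.p6, 2902 were matched as synonyms and 903 were not found; symbols are printed as deposited. No genome was used.

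Values were computed in R 4.3.3 with limma 3.58.1, and naming and figures in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9. Per tissue, neqc corrected the background from the detection p-values, added an offset of 16, quantile normalized the 8 arrays and took log2. The probe with the highest mean over all 16 arrays stood for a gene with several. A gene was tested when its probe had a detection p under 0.05 on at least 4 of the 8 arrays. FK866 was compared with control within each tissue by limma's moderated test with Benjamini-Hochberg adjustment and a threshold of 0.05, and the islet change with the hepatocyte change by the interaction in a fit of all 4 groups. Errors of log2 changes are limma's SE and intervals cover 95%. Where a named gene was detected on no array of a group, its change is given as at least a fold, the brighter group's mean against the mean, per array of the other group, of the higher of the gene's own value and the lowest detected value. Signal medians were 27.1 to 30.1 on hepatocyte arrays and 15.4 to 33.1 on islet arrays, and 11018 to 11846 probes per array were detected. No pair of arrays held identical values. The number of arrays limits the precision.

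Before the data were examined, 39 gene lists of pathways, stress responses and cell type markers were fixed. A list with at least 5 tested genes was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists. Camera with the correlation estimated from the data, and fry, were run beside it. The genes to name were also fixed. They were the 10 largest increases and the 10 largest decreases per tissue past adjusted p 0.05 with all treated arrays on 1 side of all controls, leaving out uncharacterized models. They also included up to 4 called members, or else up to 2 with the largest change, of each list described, the 10 largest past the threshold in the overlap and the difference, and always Nampt, Slc12a8, the NAD synthesis and salvage genes and Sirt1. No gene passed the first part. The 12 genes per tissue with the smallest p in the fit with a replicate block were therefore named too, chosen after their values were seen.

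Replicate numbers are shared by control and treated samples. Deviations from the group means correlated at 0.385 to 0.615 across genes between hepatocyte arrays of the same number and at 0.528 to 0.926 between islet arrays. Arrays of different number and treatment correlated at -0.369 to 0.0778 and at -0.847 to 0.667. The numbers were therefore taken to pair the samples, from the data and not from a statement in the labels, and the fit with the number as a block is given where it changes a call. Errors of single genes are those of the fit without this block.

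Alternatives tried were no background correction, median scaling, joint normalization of 16 arrays, the deposited scores, no detection filter or a stricter one at 0.01, every probe tested, the mean of a gene's probes, 1 spread shared by all arrays, array weights, the replicate block, trended and robust variances, the estimated correlation, fry and each array left out. Added after seeing the data were fits without both arrays of a number, fits joining the block with other settings, and the deposited scores with islet values left in place. The pipeline was tested on simulated data with independent noise per gene and array and 50 genes changed per size, from 0.5 to 3 log2. Data for the fit without the block were drawn without differences between pairs, which the real arrays show. The recovery of that fit may thus not hold for the real arrays. False calls are those of the whole run over all sizes. At a log2 change of 1 it recovered 88% in hepatocytes without the block and 92% with it, with 7 and 3 false calls among 8563 genes. In islets it recovered 28% and 66%, with 10 and 1 false calls among 8918 genes. At a log2 change of 2 islets gave 76% and 92%.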

Results

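The data describe the RNA response of mouse primary hepatocytes and primary pancreatic islets to FK866, which blocks nicotinamide phosphoribosyltransferase (NAMPT), the enzyme that makes nicotinamide mononucleotide from nicotinamide on the way to NAD. The stated purpose was to see what NAD depletion does. Each of the 4 groups had 4 arrays, with hepatocytes given FK866 at 200 nM and islets at 10 nM for 48 h, and controls of either tissue the DMSO vehicle alone at 0.1%. Values are normalized log2 signals. Between 11018 and 11846 of 25697 probes were detected per array.

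The control arrays carried the transcripts of their tissue. The insulin gene Ins1, detected on all of them, was higher in islets than in hepatocytes by 9.22 log2 (SE 0.14). The insulin gene Ins2 and the glucagon gene Gcg were detected on 0 of 4 hepatocyte control arrays and were at least 956-fold and 820-fold higher in islets. The liver-secreted Mup1 and Apoa1 were detected on 0 of 4 islet control arrays and were at least 874-fold and 173-fold higher in hepatocytes. Of the hepatocyte markers 19 of 20 were higher in hepatocytes, and of the beta cell markers 15 of 16 were higher in islets, by limma at adjusted p 0.05 with n = 4 arrays per group. Markers of alpha, delta and PP cells were higher in islets for 8 of 10 genes, and macrophage markers for 10 of 11.

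Both islet arrays numbered 2 stood apart from the other islet arrays. Their median signals were 15.4 in the control and 18.0 with FK866, against 26.9 to 33.1 on the other islet arrays. Their median correlations with the other islet arrays were 0.837 and 0.919, against 0.975 to 0.990. Against the other arrays of their group, fibroblast and stellate markers were higher on them by a median of 1.25 and 0.82 log2 and endothelial markers by 0.61 and 0.62. Acinar markers differed by -1.07 and -0.84, and alpha, delta and PP cell markers by -0.66 and -1.01. Beta cell markers differed by -0.01 and 0.07.

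**Figure D1:**
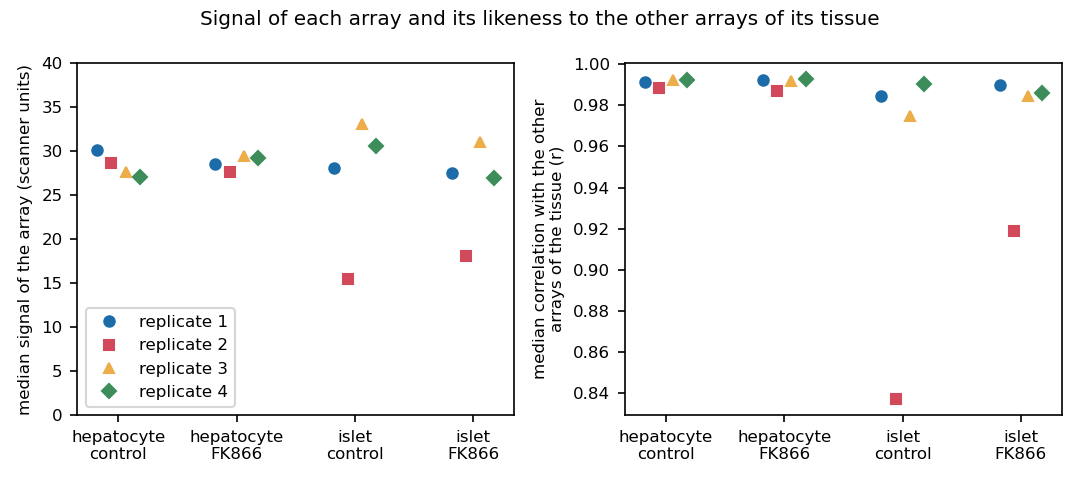
Median signal of each array in scanner units (left) and its median correlation across probes with the other arrays of its tissue (right, axis not from 0), by group; each point is 1 array and its shape the replicate number. The islet arrays numbered 2 lie at signals of 15.4 and 18.0 and correlations of 0.837 and 0.919, apart from the other islet arrays.

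The NAD pathway was examined first, since it holds the target of the drug. In hepatocytes Nampt RNA differed by -0.09 log2 between FK866 and control (SE 0.12, 95% interval -0.37 to 0.18, n = 4 arrays per group). Naprt1, which starts NAD synthesis from nicotinic acid, differed by 0.07 (SE 0.15) and Qprt, which acts in the route from tryptophan, by -0.01 (SE 0.18). Kynu differed by -0.05 (SE 0.21), Afmid by -0.05 (SE 0.16), the NAD kinase Nadk by -0.06 (SE 0.07), Nudt12 by -0.11 (SE 0.11) and the ectonucleotidase Nt5e by 0.11 (SE 0.22). The NAD-dependent deacetylase Sirt1 differed by 0.05 (SE 0.08). Probes of Naprt1 and of Afmid disagreed in sign in hepatocytes. The 8 measured genes of NAD synthesis and salvage, 2 of them higher, had a median of -0.05 and did not pass (limma camera, adjusted p = 0.811).

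In islets Nampt differed by 0.11 log2 (SE 0.18, 95% interval -0.31 to 0.52, n = 4 arrays per group). Nmnat2 and Nmnat3, which turn nicotinamide mononucleotide into NAD, differed by 0.25 (SE 0.19) and -0.01 (SE 0.39), with Nmnat2 detected on 1 of 4 control arrays. Naprt1 differed by -0.49 (SE 0.48), Afmid by -0.12 (SE 0.16), Nadk by 0.08 (SE 0.20), Nudt12 by 0.24 (SE 0.42) and Sirt1 by 0.33 (SE 0.54). In pairs 1 to 4 Sirt1 differed by 0.33, 1.395, -0.07 and -0.33 and Nampt by -0.11, 0.50, 0.02 and 0.03. Both were highest in pair 2, whose arrays stood apart. The 7 measured NAD genes, 4 of them higher, had a median of 0.08 (limma camera, adjusted p = 0.733). In both tissues limma called 0 of these genes over all genes and 0 when adjusted over the list alone, with or without the replicate block, and 0 had an unadjusted p under 0.05 without it. Slc12a8, the transporter gene in the title of the series, was detected on 0 of 8 hepatocyte arrays and 1 of 8 islet arrays and could not be tested. Without the detection filter it differed by 0.08 log2 in hepatocytes (95% interval -0.16 to 0.32) and 0.03 in islets (-0.50 to 0.57).

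In hepatocytes, the question was which genes 200 nM FK866 changed. At least as many lists as the 3 given here passed in 30 of 35 splits of the 8 arrays, so chance is not excluded for them. Genes of the cell cycle fell, with 33 of 35 measured members lower and a median of -0.13 log2 (limma camera, adjusted p = 0.0172, n = 4 arrays per group; adjusted p = 0.997 with an estimated correlation). The fall was largest in pair 2, with a median of -0.37 against -0.10, -0.00 and 0.02 in pairs 1, 3 and 4. Birc5, which acts in chromosome segregation and cell survival, differed by -0.32 (SE 0.29) and Cenpa, the histone variant of centromeres, by -0.30 (SE 0.38). Glycolysis genes rose, with 15 of 17 higher and a median of 0.08 (adjusted p = 0.0172, or adjusted p = 0.997 with an estimated correlation). Its medians in the 4 pairs were 0.20, 0.19, -0.05 and -0.02, so the rise lay in 2 pairs. Hk1, which phosphorylates glucose, was not detected on control arrays 1 and 2 and differed by 0.40 (SE 0.18), with 0.66 and 0.88 in pairs 1 and 2 against 0.05 and 0.0050 in pairs 3 and 4, and the liver pyruvate kinase Pklr by 0.25 (SE 0.11). Targets of hypoxia-inducible factors rose, with 13 of 14 higher and a median of 0.08 (adjusted p = 0.0496, or adjusted p = 0.997 with an estimated correlation). Egln1, an oxygen-dependent prolyl hydroxylase, differed by 0.22 (SE 0.14) and Mxi1, an antagonist of Myc, by 0.22 (SE 0.19). Egln1 was not detected on control array 1 and FK866 array 2, so the size of its change is uncertain. In pairs 1 to 4 it differed by 0.65, -0.18, 0.29 and 0.13.

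The other 32 of the 35 lists tested in hepatocytes did not pass, with medians from -0.08 to 0.07 and adjusted p from 0.458 to 0.994. Bile acid genes had a median of -0.08 (10 of 13 lower, adjusted p = 0.458) and cholesterol synthesis genes of 0.07 (14 of 20 higher, adjusted p = 0.458). The ATF4 and integrated stress response list had a median of 0.05 (28 of 38 higher, adjusted p = 0.486). The median of the 64 oxidative phosphorylation subunits was -0.01 (40 lower), and that of the 20 hepatocyte markers was -0.01 (adjusted p = 0.872). Median, mean and test differed in sign for 9 of these lists, none of them past the threshold, among them TCA cycle, gluconeogenesis, PPAR alpha targets and acute phase proteins. The lists tested hold 1181 genes of the score table, of which only those that met the detection filter were tested. By limma 0 of the tested ones passed over all genes and 0 when adjusted over the list alone. With the replicate block 0 passed over all genes and 3 fibroblast and stellate markers when adjusted over the list alone, which were Acta2 with 0.34 (SE 0.21), Tagln with 0.45 (SE 0.19) and Dcn with -0.24 (SE 0.19), with the errors of the fit without the block.

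In the fit with the replicate block the cell cycle call remained (adjusted p = 1.55e-06, or adjusted p = 0.961 with an estimated correlation), and glycolysis and hypoxia-inducible factor targets missed the threshold (both adjusted p = 0.0551). The cell cycle medians of the 4 pairs were -0.10, -0.37, -0.00 and 0.02. Without both hepatocyte arrays numbered 2 the cell cycle median was -0.04 against -0.13 and its call was lost, with the block (adjusted p = 0.380) and without it (0.695), and the blocked call was kept without pair 1 (median -0.14), 3 (-0.15) or 4 (-0.18). Without both arrays numbered 2, hypoxia-inducible factor targets were past the threshold in the blocked fit (median 0.13, adjusted p = 0.0186). The glycolysis medians in blocked fits were 0.02 without pair 1 (adjusted p = 0.603), 0.03 without pair 2 (0.380), 0.11 without pair 3 (0.00983) and 0.08 without pair 4 (0.0404). Those of hypoxia-inducible factor targets were 0.04 without pair 1 (0.973), 0.14 without pair 3 (0.0783) and 0.10 without pair 4 (0.0404), with 0.22, 0.02, 0.03 and 0.07 in the 4 pairs. Without pair 4 bile acid genes (median -0.09, adjusted p = 0.0404) and the ATF4 list (0.05, 0.0202) also passed, each at adjusted p = 0.957 with an estimated correlation. Without the FK866 array numbered 2 the cell cycle median turned to 0.09 (adjusted p = 0.178), and the call was also lost without control arrays 3 (median -0.08, adjusted p = 0.247) or 4 (-0.05, 0.464). It was kept, with medians of -0.26, -0.20 and -0.27, without control array 2 or FK866 arrays 3 or 4. The glycolysis call was lost without control arrays 1 (median 0.06, adjusted p = 0.169) or 2 (0.05, 0.364) or FK866 arrays 1 (0.07, 0.0812) or 4 (0.04, 0.273), and its median was 0.12 without control array 4. The hypoxia call was lost without control arrays 1 (median 0.04, adjusted p = 0.466) or 3 (0.11, 0.123) or FK866 arrays 1 (0.12, 0.0963) or 4 (0.09, 0.273), and its median was 0.13 without FK866 array 2.

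Of 8563 genes tested in hepatocytes, limma called 0 at an adjusted p of 0.05, with 145 at an unadjusted p under 0.05. Chance would give 428 for unpaired arrays. This fit counts differences between pairs as error, so fewer are due. The 7 other splits that part the arrays of every pair gave a median of 114 and up to 184. The replicate block also called 0 (535 at unadjusted p under 0.05), as did trended and robust variances (102). For 99.3% of the genes the 95% interval of the change lay within 2-fold in either direction. The genes with the smallest p in the blocked fit, chosen after their values were seen, did not pass (adjusted p from 0.571). Their errors below are those of the fit without the block. With the block they were smaller, such as 0.09 for Lox and 0.07 for Akap12. Speer3 was detected on 0 of 4 control arrays and was at least 1.34-fold higher with FK866 (adjusted p = 0.571 with the block). Cdcp1 differed by 0.52 log2 (SE 0.15), Masp1, a protease of the lectin complement pathway, by 0.59 (SE 0.31), and the actin-binding calponin Cnn2 by 0.49 (SE 0.10). The collagen cross-linking enzyme Lox differed by 0.48 (SE 0.45), Fads6 by 0.46 (SE 0.15), Akap12 by 0.44 (SE 0.25) and Accs by 0.31 (SE 0.14). Plscr4, detected on 2 of 4 FK866 arrays, differed by -0.53 (SE 0.23), Acsm3 by -0.38 (SE 0.27) and the retinol-binding Rbp2 by -0.33 (SE 0.12). Syn3 was detected on 0 of 4 FK866 arrays and was at least 1.13-fold higher in controls.

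**Figure D2:**
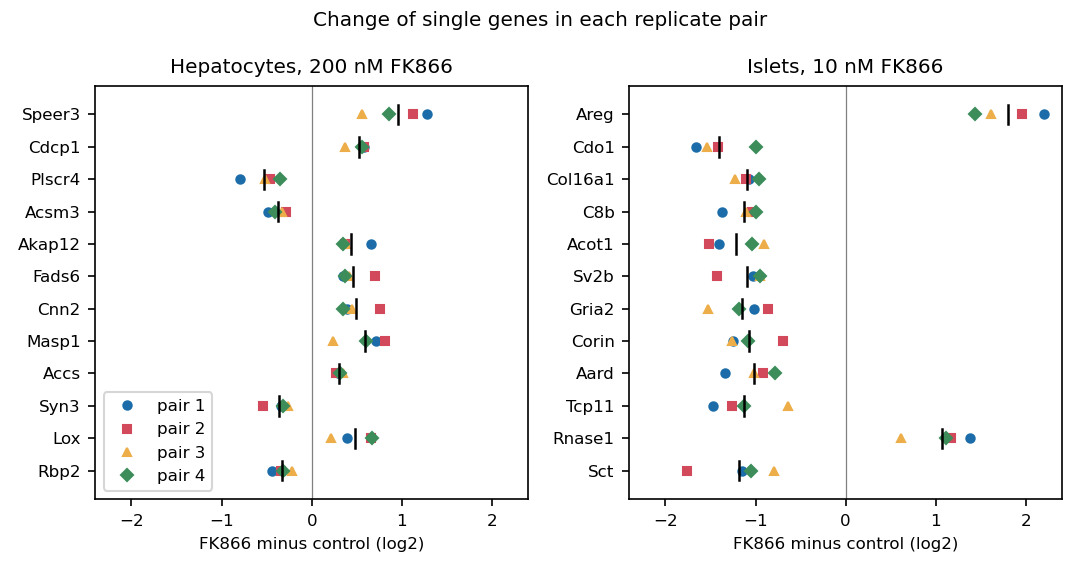
Log2 change between FK866 and control within each replicate pair (points, 1 per pair) and over all pairs (black bars) for the 12 genes per tissue with the smallest p in the fit with the replicate block. Islet changes of Areg lie between 1.44 and 2.20 in the 4 pairs; it alone passed the adjusted threshold.

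In islets, the same question was asked of 10 nM FK866. At least as many lists as the 7 given below passed in 6 of 35 splits of the 8 arrays, so chance is not excluded for them. Heat shock genes rose, with 17 of 20 measured members higher and a median of 0.19 log2 (limma camera, adjusted p = 0.00036, n = 4 arrays per group; adjusted p = 0.336 with an estimated correlation). The chaperone Hspa8 differed by 1.46 (SE 1.09) and the small heat shock protein Hspb8 by 0.66 (SE 0.36). Endoplasmic reticulum chaperones and folding factors rose, with 18 of 20 higher and a median of 0.24 (adjusted p = 0.0054, or adjusted p = 0.364 with an estimated correlation). Edem1, which acts in degradation of misfolded glycoproteins, differed by 0.76 (SE 0.73) and the calcium-binding chaperone Calr by 0.72 (SE 0.77). Both were higher in 2 of 4 pairs only, Edem1 by 1.06 and 2.17 and Calr by 0.72 and 2.51 in pairs 2 and 3, against -0.09 and -0.08 and -0.09 and -0.24 in pairs 1 and 4. Hspa8 differed by 1.94 and 3.57 in pairs 2 and 3 against 0.14 and 0.18 in pairs 1 and 4. Fibroblast and stellate markers had medians of -0.03, -0.58, -0.51 and -0.01 in pairs 1 to 4, against 0.06, 0.53, 0.12 and -0.05 for the chaperone list and 0.19, 0.44, 0.03 and 0.12 for the heat shock list. The larger changes of Edem1, Calr and Hspa8 thus lay in the pairs where markers of another cell type were lower, and the cause was not tested. Edem1 was not detected on control arrays 2 and 3. Proteasome subunits rose, with 23 of 26 higher and a median of 0.13 (adjusted p = 0.00904, or adjusted p = 0.469 with an estimated correlation). Their pair medians were 0.07, 0.25, 0.18 and 0.06, also larger in pairs 2 and 3. Psmb7 differed by 0.42 (SE 0.85) and Psmb6 by 0.34 (SE 0.21). In pairs 1 to 4 Psmb7 differed by 0.04, 1.24, 0.41 and -0.02, so its change lay mainly in pair 2.

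Targets of ATF4 and the integrated stress response rose in islets, with 29 of 37 higher and a median of 0.10 (limma camera, adjusted p = 0.00904, or adjusted p = 0.410 with an estimated correlation). The secreted stress cytokine Gdf15 differed by 1.00 (SE 0.91) and Phgdh, the first enzyme of serine synthesis, by 0.72 (SE 0.86). Neither was detected on control array 2, so their changes in pair 2 have no measured control. In the other pairs Gdf15 differed by 0.20 to 0.78 and Phgdh by -0.06, 2.23 and -0.35. Cytosolic ribosomal protein genes rose, with 33 of 38 higher and a median of 0.10 (adjusted p = 0.0147, or adjusted p = 0.400 with an estimated correlation). Their pair medians were 0.06, 0.16, 0.14 and 0.04, also larger in pairs 2 and 3, where the fibroblast and stellate markers were lower. Rps6 differed by 0.33 (SE 0.33) and Rps7 by 0.29 (SE 0.35). PPAR alpha targets fell, with 7 of 8 lower, a median of -0.25 and a mean of -0.31 (adjusted p = 0.00515, or adjusted p = 0.336 with an estimated correlation). Acot1, an acyl-CoA thioesterase, was detected on 4 of 4 control and 0 of 4 FK866 arrays, at least 2.00-fold higher in controls, and passed when adjusted over the list alone but not over all genes (adjusted p = 0.974). Pdk4, which inhibits pyruvate dehydrogenase, differed by -0.72 (SE 0.73, or 0.14 with the replicate block). In pairs 1 to 4 it differed by -0.95, -0.89, -0.59 and -0.45, and it did not pass over all genes with the block (limma, adjusted p = 0.157). Interferon-stimulated genes fell, with 13 of 18 lower and a median of -0.17 (adjusted p = 0.0311, or adjusted p = 0.336 with an estimated correlation); Oasl2 differed by -0.64 (SE 0.31) and Bst2, against the list and not detected on control array 2, by 0.59 (SE 0.35). On the deposited scores the interferon median had the other sign, at 0.022 score units (adjusted p = 0.550), and the call was lost.

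**Figure D3:**
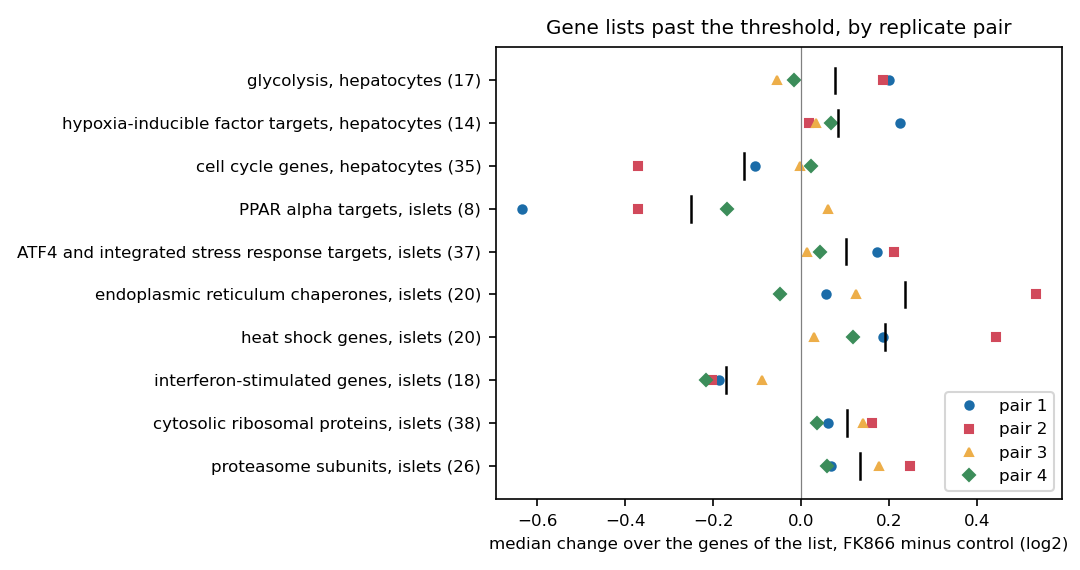
Median log2 change between FK866 and control over the measured genes (number in brackets) of each list past the threshold, within each replicate pair (points) and from the group means (black bars). Interferon-stimulated genes lie below 0 in all 4 islet pairs, at -0.22 to -0.09, and endoplasmic reticulum chaperones reach 0.53 in pair 2 and -0.05 in pair 4.

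With the replicate block all 7 islet lists kept their call, and with an estimated correlation in that fit 0 did (adjusted p from 0.628 to 0.664). When a pair was left out of that fit, heat shock genes kept theirs in each case (medians from 0.10 to 0.24), and PPAR alpha targets lost theirs in each, without pairs 1 (median -0.14, adjusted p = 0.402), 2 (-0.24, 0.375), 3 (-0.35, 0.0702) or 4 (-0.30, 0.278). Interferon-stimulated genes lost theirs without pairs 1 (-0.15, 0.134), 3 (-0.15, 0.0684) or 4 (-0.12, 0.208) and the ATF4 list without pair 1 (0.04, 0.150). Ribosomal proteins (0.08, 0.139) and proteasome subunits (0.12, 0.0682) lost theirs without pair 3, and endoplasmic reticulum chaperones without pair 2 (0.07, 0.0855). Oxidative phosphorylation subunits also rose in that fit, with 48 of 64 higher and a median of 0.09 (adjusted p = 0.0137, or adjusted p = 0.826 with an estimated correlation). Atp5f1 differed by 0.45 (SE 0.96 without the block, 0.20 with it) and was higher in 3 of 4 pairs. Atp5o differed by 0.44 (SE 0.56 without the block, 0.13 with it) and was higher in 4 of 4. Neither passed over all genes with the block (limma, adjusted p = 0.437 and 0.309). Fibroblast and stellate markers fell in the blocked fit, with 11 of 14 lower and a median of -0.25 (adjusted p = 0.0137, or adjusted p = 0.685 with an estimated correlation). The collagens Col1a1 and Col5a1 differed by -0.87 (SE 0.70 without the block, 0.35 with it) and -0.84 (SE 0.60 without it, 0.26 with it). Col1a1 was higher in 2 of 4 pairs, and neither was detected on FK866 arrays 1 and 3 or control array 1. On the control and FK866 arrays numbered 2, oxidative phosphorylation genes were shifted by -0.78 and -0.48 against the other arrays of the group, endoplasmic reticulum chaperones by -0.83 and -0.46, and proteasome subunits by -0.53 and -0.39. Heat shock genes were shifted by -0.16 and 0.09, PPAR alpha targets by 0.02 and -0.39 and interferon-stimulated genes by -0.06 and 0.19. The ATF4 list was shifted by -0.02 and 0.21 and ribosomal proteins by -0.15 and -0.12.

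Without both arrays numbered 2, the lists still past the threshold were proteasome subunits (median 0.11, adjusted p = 0.00656), ribosomal proteins (0.10, 0.0131) and heat shock (0.10), ATF4 (0.09) and interferon-stimulated genes (-0.14), each at 0.0286. The chaperone call was lost with a median of 0.07 against 0.24 (adjusted p = 0.102), and the PPAR alpha call with a median of -0.24 against -0.25 (adjusted p = 0.310). Without both of these arrays in the blocked fit, oxidative phosphorylation (adjusted p = 0.381) and fibroblast markers (0.375) were lost, as they were without pair 3. Several of the rises depended on single arrays. Without control array 2 alone the median was 0.0029 for proteasome subunits (adjusted p = 0.504), 0.0011 for ribosomal proteins (0.298) and 0.08 for chaperones (0.504), and without control array 1 alone that of the ATF4 list was 0.0035 (0.442). Without control array 3 the chaperones (median 0.23, adjusted p = 0.0702), proteasome subunits (0.18, 0.0702) and ribosomal proteins (0.07, 0.299) were lost, and without FK866 array 1 the ribosomal proteins (0.08, 0.101). Without FK866 array 2 the ATF4 list (0.06, 0.362) was lost, and proteasome subunits were kept at 0.24. The ATF4 median was 0.15 without control array 3 or FK866 array 1, and the proteasome median 0.20 without control array 4. The interferon call was lost without control arrays 1 (median -0.14, adjusted p = 0.442), 2 (-0.14, 0.0721) or 4 (-0.17, 0.447) or FK866 arrays 2 (-0.22, 0.295) or 3 (-0.07, 0.243). The PPAR alpha call was lost without control arrays 1 (median -0.24, adjusted p = 0.525), 2 (-0.19, 0.106), 3 (-0.27, 0.167) or 4 (-0.24, 0.428) or FK866 array 2 (-0.09, 0.397), and its median was -0.16 without FK866 array 1. The heat shock call held without each single array (adjusted p up to 0.0332), with a median of 0.11 without FK866 array 2.

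The other 30 of the 37 lists tested in islets did not pass without the block, with medians from -0.28 to 0.12 and adjusted p from 0.0536 to 0.976. Cell cycle genes had a median of -0.14 (12 of 18 lower, adjusted p = 0.0536), beta cell markers of -0.11 (10 of 16 lower, adjusted p = 0.250; medians of -0.26, 0.13, -0.15 and -0.14 in the 4 pairs) and genes of insulin secretion of -0.00 (adjusted p = 0.688). In blocked fits without a pair, some lists passed that had passed neither with nor without the block on all arrays. These were beta cell markers without the islet arrays numbered 2 (median -0.17, 12 of 16 lower, adjusted p = 0.0494, or adjusted p = 0.687 with an estimated correlation) and gluconeogenesis without pair 1 (-0.35, adjusted p = 0.0294) or pair 3 (-0.29, 0.0310). Without pair 1 they were also cell cycle genes (-0.19, 0.0321) and genes disallowed in beta cells (0.16, 0.0304), and with an estimated correlation these 4 had adjusted p of 0.828 or 0.842. Cell cycle genes also passed on all arrays with no background correction, no detection filter, the stricter filter, every probe tested or the mean of probes. Endothelial markers had a median of 0.12 (adjusted p = 0.0798) and gluconeogenesis genes of -0.28 (5 of 7 lower, adjusted p = 0.280). Median, mean and test differed in sign for 3 lists, namely P450 and xenobiotic metabolism, acinar markers and duct markers. The lists tested hold 1234 genes of the score table, of which only those that met the detection filter were tested. Of the tested ones 0 passed over all genes and 3 when adjusted over the list alone. These were Acot1, the P450 gene Cyp3a13 with 0.73 (SE 0.20) and the secretin gene Sct with -1.19 (SE 0.26). With the replicate block 0 passed over all genes and 21 when adjusted over the list alone, 7 higher and 14 lower with FK866, in 11 lists. They included 5 genes each of the P450 and the hepatocyte secreted lists and 2 each of the gluconeogenesis, PPAR alpha, acinar and alpha, delta and PP cell lists. Among them were the gluconeogenic Fbp1 with -0.72 (SE 0.49) and Slc37a4 with -0.78 (SE 0.52), the lipogenic regulator Srebf1 with -0.57 (SE 0.19) and the retinol carrier Rbp4 with 0.72 (SE 0.36), chosen after their values were seen and given with the errors of the fit without the block.

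Of 8918 genes tested in islets, limma called 0 at an adjusted p of 0.05, with 121 at an unadjusted p under 0.05. Chance would give 446 for unpaired arrays. This fit counts differences between pairs as error, so fewer are due. The 7 other splits that part the arrays of every pair gave a median of 25 and up to 31. The fit with the replicate block called 1 (1032 at unadjusted p under 0.05) and trended and robust variances without the block 0 (105). For 66.0% of the genes the 95% interval lay within 2-fold, and for 95.5% with the block. Areg, which encodes the EGF receptor ligand amphiregulin, was the gene called with the block. It rose by 1.80 log2 (SE 0.37 without the block, 95% interval with it 1.44 to 2.17, adjusted p = 0.0277) and was higher with FK866 in 4 of 4 pairs, from a control mean of 9.37 ± 0.68 to 11.17 ± 0.45 (SD, n = 4). Its blocked call was lost without the pairs numbered 1 (adjusted p = 0.0528), 2 (0.153) or 3 (0.240), and in the blocked fit on the deposited scores, where 0 islet genes passed (adjusted p = 0.343 for Areg).

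The next genes by p in the blocked islet fit, chosen after their values were seen, did not pass. Their errors below are those of the fit without the block. With the block they were smaller, such as 0.16 for Tcp11. The cysteine dioxygenase gene Cdo1, detected on 4 of 4 control and 1 of 4 FK866 arrays so that the size of its change is uncertain, differed by -1.40 (SE 0.35), the collagen gene Col16a1 by -1.09 (SE 0.24) and the complement gene C8b by -1.12 (SE 0.23), each at adjusted p = 0.0507 with the block. Corin, a protease that activates natriuretic peptides, was detected on 0 of 4 FK866 arrays and was at least 1.37-fold higher in controls (adjusted p = 0.0779 with the block). The synaptic vesicle gene Sv2b differed by -1.09 (SE 0.32), the glutamate receptor gene Gria2 by -1.14 (SE 0.34), Aard by -1.01 (SE 0.30) and Tcp11 by -1.13 (SE 0.45). The pancreatic ribonuclease Rnase1, one of the acinar markers, differed by 1.07 (SE 0.35).

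The islet and hepatocyte responses were then compared, with the limit that tissue and dose differ together. Heat shock genes changed more upward in islets, by a median of 0.18 log2 (limma camera on the interaction, adjusted p = 0.000722, or adjusted p = 0.244 with an estimated correlation). The same held for endoplasmic reticulum chaperones (0.27, adjusted p = 0.00721, or adjusted p = 0.382 with an estimated correlation). It held for proteasome subunits (0.14, adjusted p = 0.0333) and ribosomal proteins (0.10, adjusted p = 0.0234), each with adjusted p = 0.560 with an estimated correlation. PPAR alpha targets changed more downward in islets (-0.37, adjusted p = 0.00259, or adjusted p = 0.0921 with an estimated correlation). So did fibroblast and stellate markers (-0.25, adjusted p = 0.00721) and interferon-stimulated genes (-0.19, adjusted p = 0.0238), each with adjusted p = 0.560 with an estimated correlation.

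Of 7522 genes tested in both tissues, limma called 0 as different, with 83 at an unadjusted p under 0.05, and 0 with trended and robust variances (76). Chance would give 376 for unpaired arrays, but these fits count differences between pairs as error, so fewer are due. The replicate block called 3 (734 at unadjusted p under 0.05). In it Areg differed by 1.76 log2 between the tissues (adjusted p = 0.00952), Cdo1 by -1.34 (adjusted p = 0.0146) and C8b by -1.14 (adjusted p = 0.0287). Of 8 blocked fits without 1 pair, Areg was called as different in 6, Cdo1 in 1 (without islet pair 4) and C8b in 1 (without islet pair 2). No gene was called without hepatocyte pair 1 (lowest adjusted p = 0.0696) or 4 (0.0750), nor in the blocked fit on the deposited scores (0.0952). It also called oxidative phosphorylation subunits as more upward in islets (median 0.08, adjusted p = 0.0200, or adjusted p = 0.840 without the block and with an estimated correlation).

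The overlap of the responses was tested last. By limma 0 genes were called in the same direction in both tissues, with or without the replicate block. At an unadjusted p under 0.05 in the blocked fits, 19 genes were higher in both, among them the stress-induced transcription factor Atf3, the cationic amino acid transporter Slc7a3 and Marcks, against 9.55 for independent lists (one-sided Fisher's exact test, p = 0.00315). Lower in both were 16 genes, among them the gluconeogenic Fbp1, the glycerol phosphate dehydrogenase Gpd1 and Fmo1, against 8.78 (p = 0.0145, same exact test). In hepatocytes the blocked fit had 199 of the genes tested in both higher and 184 lower at that p. Chance would give 376 in the 2 directions together, so the hepatocyte list lay near chance. Fisher's test takes genes as independent, and overlap in opposite directions was not counted, so a shared response is not shown. Without the block 0 genes were higher in both against 0.176, and 1 was lower against 0.306 (p = 0.265, same exact test). Across the 7522 genes, which are not independent replicates, the changes in the tissues correlated at r = 0.000563 and rho = 0.00692, and 50.4% had the same sign.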

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

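The fits without both islet arrays numbered 2 and the shifts of gene lists on these arrays were chosen after the arrays had been seen to stand apart; the tests of dimness and of sample quality were set before their results were seen. Of 140 groups of 4 arrays examined, 24 had 1 array whose gap to its nearest neighbour took more of the group's range than Dixon's 95% critical value allows. Chance flags about 1 in 20 groups, here 7. Of the 24 groups, 20 were islet groups, and in 19 of these the distant array was replicate 2.

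The distance was seen first in measures of whole arrays. The share of the range was 0.846 for detected probes in islet controls, where replicate 2 had 11092. For the correlation with the other arrays of the tissue it was 0.899 in islet controls and 0.924 in FK866-treated islets, and 0.831 and 0.847 in control and treated hepatocytes, each with replicate 2 lowest. The hepatocyte arrays numbered 2 correlated at 0.988 and 0.987 with the others, a far smaller distance than in islets.

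Replicate 2 was also the distant array for single islet genes. In FK866-treated islets it was lowest for Atp5f1 (0.933), Atp5o (0.885), Pdk4 (0.874), Gdf15 (0.835), Phgdh (0.892), Edem1 (0.864), Hspa8 (0.965), Psmb7 (0.944) and Psmb6 (0.836), and highest for Naprt1 (0.862), Cdo1 (0.875) and C8b (0.869). In control islets it was lowest for Sirt1 (0.865), Gdf15 (0.931), Psmb7 (0.840) and Psmb6 (0.830). Replicate 1 was the distant array for Nmnat2 in control islets (0.861), Egln1 in control hepatocytes (0.865) and Masp1 in treated hepatocytes (0.876).

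Dimness and sample quality were weighed for the islet arrays numbered 2. Their deviations from their groups correlated with each other across 8918 genes at 0.926, and still at 0.925 after a trend on signal level was removed. A smooth trend on signal level thus does not account for them. The values had been quantile normalized before this test, so it cannot weigh other effects of dimness. Lower RNA or sample quality stays open, since the deviations of paired probes of 2121 genes correlated at 0.557 (Spearman, 95% bootstrap interval 0.522 to 0.591), below the 0.879 that the same probes gave for the islet to hepatocyte difference but not low enough to show loss of gene signal. The SD of the deviations over genes was 1.22 and 0.86 log2 against 0.28 for other islet arrays, and 204 genes lay over 2 log2 away on both arrays in the same direction. The shared deviation covers control and treated arrays alike, and no biological explanation was tested because the design names none.

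The effect of FK866 differed between islets and hepatocytes for 7 gene lists by the interaction in limma camera. The differences in median log2 change, islets minus hepatocytes, were -0.366 for PPAR alpha targets, 0.271 for endoplasmic reticulum chaperones, 0.184 for heat shock genes, -0.193 for interferon-stimulated genes, 0.0997 for ribosomal proteins, 0.138 for proteasome subunits and -0.255 for fibroblast and stellate markers. With the estimated correlation 0 of them passed (lowest adjusted p = 0.0921). Tissue and dose cannot be told apart in these differences.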

How the results depend on the processing

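The deposited scores with islet values in place, the fits without both arrays of a number and the fits joining the block with another setting were chosen after seeing the data. The count of 0 genes in each tissue held without each single array (0 to 0). Of 1729 values of single named genes under alternatives 1708 kept their side of the threshold and 21 newly passed it. A turn of sign was counted only for called genes, and 0 were called, so signs of single genes were not compared. Of 320 values of the 10 called gene lists 191 kept their call, 128 lost it and the test of 1 turned, the hepatocyte cell cycle list without FK866 array 2 (median 0.090; -0.267 to 0.090 over single arrays left out). The median of islet interferon-stimulated genes also turned with the deposited scores (0.022 score units, with or without the block, and 0.029 with islet values in place), while its test stayed downward and lost its call (adjusted p = 0.550, 0.646 and 0.817). Leaving out single arrays gave 1 to 8 hepatocyte lists, 3 to 9 islet lists, 0 to 0 genes in both tissues and 0 to 1 genes for the difference between tissues, the 1 being Ambp without islet control array 2. The cause of the following changes was not tested, except that fits without arrays hold fewer samples.

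Hepatocyte lists fell from 3 to 0 with the deposited scores, no detection filter, array weights, the estimated correlation and fry, and to 1 with the stricter filter, a shared spread and the replicate block. Islet lists fell from 7 to 4 with the deposited scores and to 0 with the estimated correlation and fry. Of the 7, only the heat shock, ATF4 and proteasome lists kept their call on the deposited scores. Hepatocyte genes rose from 0 to 2 with the deposited scores (Heatr5a, Slc10a4). Islet genes rose from 0 to 2 with a shared spread (Corin, Ramp1), 14 with array weights and 1 with the replicate block (Areg). Genes differing between tissues rose from 0 to 1 with array weights (Ambp) and 3 with the replicate block (Areg, C8b, Cdo1). The block changed no call of a gene over all genes or of a list other than those given here and in the results, and changed list-alone calls as given there.

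Among the added settings, the scores with islet values in place gave 2 hepatocyte genes, 0 hepatocyte lists and 2 islet lists. Leaving out both islet arrays 2 gave 1 gene differing between tissues, and both hepatocyte arrays 2 gave 1 hepatocyte list (hypoxia-inducible factor targets). The block with the estimated correlation or with fry gave 0 lists in hepatocytes and 0 in islets. The block on the scores gave 1 hepatocyte gene (Heatr5a), 1 hepatocyte list (cell cycle), 5 islet lists, 0 islet genes and 0 genes differing between tissues. The block with trended and robust variances gave 5 hepatocyte lists, 21 islet genes and 11 genes differing between tissues. In blocked fits without hepatocyte pair 1, 1 hepatocyte list (cell cycle) and 0 differing genes passed; without pair 2, 1 list (hypoxia-inducible factor targets, with cell cycle lost) and 1 differing gene (Areg); without pair 3, 2 lists and 1 differing gene (Areg); without pair 4, 5 lists and 0 differing genes. In blocked fits without islet pair 1, 1 differing gene (Areg) passed; without pair 2, 5 (Ambp, Areg, C8b, Cfi, Tubb2b); without pair 3, 4 islet lists and 1 differing gene (Areg); without pair 4, 1 islet gene (Areg) and 2 differing genes (Areg, Cdo1). A chip block was not run because the column names give no chip.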

Other observations

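Of the tests below, that of a rise of Slc12a8, those of the displaced columns and those of the actin list and of fibroblasts were chosen after the results they bear on had been seen; the tests of background and of other splits were set before.

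Some islet groups of genes moved differently between pairs. Acinar marker medians were 0.56, -0.00, -0.91 and 0.40 in pairs 1 to 4, against 0.05 over all (6 of 12 higher, limma camera adjusted p = 0.815). Gluconeogenesis genes were lower in all 4 pairs, at -0.24, -0.51, -0.21 and -0.25, with an adjusted p of 0.280 without the block and 0.0519 with it. Solute carriers, the family of Slc12a8, had a median of -0.05 in islets (86 of 145 lower, adjusted p = 0.745) and 0.00 in hepatocytes (73 of 137 higher, adjusted p = 0.957). Genes disallowed in beta cells had a median of 0.12 in islets (10 of 14 higher, adjusted p = 0.0965).

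Muscle-type actins and actin-binding genes had higher values in FK866-treated hepatocytes. Acta1 differed by 1.05 log2 (SE 0.24), Actc1 by 1.22 (SE 0.27), Tpm2 by 0.52 (SE 0.12) and Cnn2 by 0.49 (SE 0.10), each higher in 4 of 4 pairs and each at adjusted p = 1.00 in limma over all genes. A hypothesis was that the wider set of actin cytoskeleton and serum response factor targets moves with them. A list written after this was seen gave, for 30 other genes, a median of 0.11 (95% bootstrap interval over genes 0.04 to 0.14, 25 higher, blocked limma camera p = 1.77e-06, or p = 0.0123 with an estimated correlation), with 0 genes called; among its members Tagln differed by 0.45 and Acta2 by 0.34. Its first run held 4 more genes whose values had already been seen and gave 34 genes, a median of 0.11 and an estimated p of 0.0165. Pair medians were 0.12, 0.07, 0.09 and 0.07, and leaving pairs out gave estimated p of 0.0441, 0.0385, 0.0614 (pair 3) and 0.0346.

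No such rise was seen in islets, where 29 genes of the list had a median of -0.022 (95% bootstrap interval over genes -0.11 to 0.03). This interval leaves out the spread between arrays, so it cannot exclude a shift of the hepatocyte size in islets. More fibroblasts or stellate cells in the treated hepatocyte cultures stay possible, since 9 of their markers outside the list had a median of 0.00048 with an interval of -0.15 to 0.18. Of these 9, Thy1 differed by 0.30, Col5a1 by 0.18, Vim by 0.15, Sparc by 0.03 and Timp1 by 0.00048. Reln differed by -0.03, Ecm1 by -0.07, Fbln1 by -0.15 and Dcn by -0.24. In hepatocytes 11 of 23 markers were measured, 2 of them (Acta2 and Tagln) also in the actin list. Chance was not excluded either, since 2 of the 35 splits of the 8 arrays gave a p as small as 9.17e-06, with 1.59e-06 in the best other split; among the 8 splits that part every pair the real one had the smallest p (next 0.00664), and 8 are too few for a share under 0.05. A coordinated rise of actin genes may thus be present in hepatocytes, as a hypothesis from the data it was tested on.

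Slc12a8 had higher deposited scores with FK866, by 0.244 in hepatocytes and 0.264 in islets. The lowest score of the islet controls, -1.22 on array 4, was the floor of that array. The other islet controls scored -0.22, 0.12 and 0.10, against -0.25 to 0.06 with FK866, so the islet difference rested on that 1 array. In hepatocytes control array 2 and FK866 array 3 lay at their floors, at -1.15 and -1.16. Of 4320 other genes with 1 probe detected on at most 1 array, 46 or 1.06% (95% interval 0.781 to 1.42) had score differences at least as large in both tissues, so values at background reach this size seldom but do reach it. A rise of Slc12a8 RNA by FK866 also stays open, as the probe was detected on 0 of 8 treated arrays and the only detection was on an islet control array. These explanations cannot be told apart because the probe signals, from -6.87 to 43.9, lie at background.

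In the stretch of the score table where hepatocyte and islet values of a symbol held different probes, 3499 of 3499 genes compared (100%) had islet values matching the hepatocyte values of the next symbol, and 13 of 3005 (0.433%) those of their own. To ask which side is displaced, 7 beta cell and hepatocyte markers were compared, of which 4 were brighter in their own tissue only under the hepatocyte naming and 0 only under the islet naming (exact sign test, p = 0.125). Later forms, chosen after this result, used 15 genes of 7 lists and gave 6 against 1 (exact sign test, p = 0.125) and a mean difference of 2.58 log2 (exact sign-flip permutation, p = 0.0114) in favour of the hepatocyte naming. The last form returned to the 7 markers with the size of their ratios, and the log2 ratio of own to other tissue was higher under the hepatocyte naming by a mean of 4.67 (95% bootstrap interval over genes 1.89 to 7.39, exact sign-flip permutation, p = 0.0312), which argues against displaced hepatocyte columns. Under the islet naming Ins1 would have signals of 2644.1 to 3036.2 in hepatocytes and 1463.2 to 3159.3 in islets, against 49.1 to 87.9 and 38694.3 to 64040.7 under the hepatocyte naming; of the 7 markers Mafa alone had a higher ratio under the islet naming (0.63 against 0.48).

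Other splits of the arrays were set against the real one. In hepatocytes all 35 splits gave at least the 0 genes called (highest other 7), and 30 of 35 gave at least the 3 lists (highest other 18), so chance is not excluded for these lists. The 3 splits that kept each pair together called a median of 15 lists and up to 18, which points to differences between replicate numbers rather than treatment. In islets the same 3 splits called a median of 1 list and up to 4, under the 7 of the real split. By genes at an unadjusted p under 0.05 they went the other way in islets, with a median of 770 and up to 1752 against 121 in the real split. In hepatocytes that median was 1177, against 145 in the real split. Among the 8 splits that part every pair, in blocked fits, 8 gave at least 0 genes (highest other 0) and 7 at least the 1 list (highest other 7). In islets 35 of 35 splits gave at least 0 genes (highest other 0), and 6 of 35 gave at least 7 lists (highest other 11), so chance is not excluded for these lists either. In these fits without the block, the 7 other splits that part every pair called a median of 2 and up to 4 lists in hepatocytes and a median of 4 and up to 10 in islets. By genes at an unadjusted p under 0.05 they gave up to 31 in islets, against 121 in the real split. In hepatocytes they gave up to 184, against 145. With the block, 1 of 8 splits, the real one, gave 1 gene (highest other 0) and 1 of 8 gave 9 lists (highest other 7), and 8 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 1032 islet genes with the block (highest other 583), and 535 hepatocyte genes (highest other 585). For the difference between tissues and for genes shared by both, 100 of 100 drawn splits gave at least 0 genes (highest other 0). Every split reaches a count of 0, so the comparisons with 0 called genes, here and above, cannot speak to chance.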
